A study of Fragaria vesca with 9 samples.

How the data were processed

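Total RNA of strawberry fruits was turned into libraries with a NEBNext Ultra kit and sequenced as paired-end reads on an Illumina NovaSeq instrument, per the labels' protocols. The deposited table holds raw read counts per gene, without normalization, for 9 libraries and 25308 genes, made by the authors. The submitters' processing notes name fastp, HISAT2, featureCounts and DESeq2 1.22.1 with no role or settings. The genome build, the annotation version, the use of strand and the treatment of reads with several matching positions are not given in the sources used here. Chromosome positions are those of the deposited table, on chromosomes 1 to 7 of its assembly. Reads of near-identical copies and of overlapping or antisense genes cannot be told apart on this basis. A reference gene table of another assembly was not used. Of the loci, 2085 carry identifiers other than FvH4 gene numbers, 157 genes lie off the 7 chromosomes, 22495 genes carry a protein description from NR and 16908 one from Swiss-Prot. One emptied line was skipped.

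The 6 mutant columns were matched to samples by line and replicate number. The 3 columns headed EV-cr with a number were assigned to the WT group as the only group left. Their numbers are not tied to a WT sample, so WT 1 to WT 3 are names only. Totals ran from 18355688 to 20721696 counts per library. A floor of 3 counts over a group of 3 libraries equals 0.0627 CPM in WT, 0.0461 CPM in FvRIF-cr-6 and 0.0448 CPM in FvRIF-cr-13. Where a group had 0 counts, the fold is a bound against this floor, and with 1 to 3 counts the ratio carries an exact 95% counting interval. Such intervals and floors cover counting error only, since the reads carry no molecular identifiers in the sources used here. No 2 libraries agreed within sampling noise: chi-square per degree of freedom was 2.81 to 16.2 within groups, over genes with at least 50 counts in the pair.

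Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr (19387) entered one fit over all 9 libraries with group as the only term, TMM factors (0.832 to 0.844 in WT, 1.06 to 1.07 in FvRIF-cr-6, 1.11 to 1.13 in FvRIF-cr-13) and the quasi-likelihood F test. The common biological coefficient of variation was 0.0950. A call is a Benjamini-Hochberg adjusted p below 0.05, and the standard error of a log2 fold change is its size over the root of F. The principal components used log2 CPM with a prior count of 2. Gene lists were tested with camera (limma 3.58.1), two-sided, with a preset correlation of 0.01 and at least 5 tested members, adjusted over the lists, and again with an estimated correlation. Figures and tables were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

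The groups, the tests, the 23 lists and the rule for named genes were fixed before the data were examined. The lists collect genes by words in their NR description: anthocyanin pathway, proanthocyanidin and flavonol branch, lignin branch, pectin-degrading enzymes, pectinesterase and polygalacturonase inhibitors, expansins with xyloglucan and glucan modifying enzymes, abscisic acid, auxin, gibberellin, ethylene, sugar, volatiles, carotenoids, photosynthesis, ascorbate, NAC, MADS-box and MYB transcription factors, heat shock proteins, pathogenesis-related proteins, seed storage and late embryogenesis, cell division and cytosolic ribosomal proteins. The rule names FvRIF and FvMYB10, and up to 2 members per list called alike in both lines at a mean of at least 10 CPM with the largest mean change (or else the most abundant member). It also names the 5 annotated genes with the largest rise and the 5 with the largest fall in both lines, and the 5 called genes with the largest rise and the 5 with the largest fall between the lines, all at a mean of at least 10 CPM. The list tests between the lines, the Pfam families, the sets of loci on or silent in a group and the tests on the seed list and on neighbouring genes were chosen after seeing the data.

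The steps were tested on simulated counts with changes of known size. For FvRIF-cr-6 vs WT 17361 genes were tested, and the simulation changed 67 genes 1.5-fold, 67 genes 2-fold and 66 genes 4-fold. The shares recovered were 64.2%, 89.6% and 100%, and 8.3% of the calls were unchanged genes. For FvRIF-cr-13 vs WT, with 17378 genes tested and as many changed ones, the shares were 61.2%, 85.1% and 100%, with 4.5% unchanged genes among the calls. Photosynthesis genes were shifted as well, and all other genes were left unchanged. In the data 78.3% of tested genes were called in FvRIF-cr-6 and 77.3% in FvRIF-cr-13, so these shares need not hold there. Shared controls were simulated in 20 runs of unchanged groups. The alternatives tried were median-of-ratios factors, total library size alone, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, glmTreat against a fold of 1.5, the 2 compared groups alone, the replicate number as a block between the lines, each library left out in turn, Swiss-Prot descriptions and the estimated correlation. Leaving out loci without FvH4 gene numbers, and leaving out FvRIF-cr-6 replicate 1 together with FvRIF-cr-13 replicate 3, were added after seeing the data.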

Results

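Read counts per gene were analysed from fruits of the woodland strawberry Fragaria vesca (strain Ruegen), taken at 28 days post anthesis from plants kept in a greenhouse. The 9 libraries fell into 3 groups of 3: wild type (WT), the mutant line FvRIF-cr-6 and a further mutant line, FvRIF-cr-13. FvRIF is a transcription factor of the NAC family, and the series title presents it as a regulator of ripening. Totals were 18355688 to 19639277 counts per library in WT, 19942840 to 20721696 in FvRIF-cr-6 and 19556093 to 20320258 in FvRIF-cr-13. The labels call the control group WT. The control columns of the count table are headed EV-cr with a number, and share cr with the mutant headings. They were taken as WT because no other group remained once the 6 mutant columns had been matched by name. Whether these plants were untransformed or carried a control construct is not settled by the sources used here. Levels below are CPM (read counts scaled to library size with TMM factors) as mean ± SD with n = 3 libraries per group. A gene rose or fell if its Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test was below 0.05. Nothing in the labels says that replicates came from separate plants, so the p-values measure the spread between these libraries, which may be technical.

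The first principal component of log2 CPM held 85.3% of the variance and separated WT from both lines. The second held 8.37% and separated the lines from each other. Within a group, log2 CPM of any 2 libraries correlated across genes at r = 0.981 or more, where genes are not independent replicates. FvRIF-cr-13 replicate 3 lay apart from its group, at -64.4 on the second component against -45.2 and -42.8 for the others. The most abundant transcript in WT came from FvH4_7g18560, annotated as vinorine synthase-like, a family of acyltransferases, at 16473 ± 129 CPM. It fell to 2339 ± 112 CPM in FvRIF-cr-6 and to 4087 ± 216 CPM in FvRIF-cr-13. In both lines the most abundant transcript came from FvH4_3g20030, a metallothionein-like gene of a family of metal-binding proteins, which rose from 3072 ± 80.4 CPM in WT to 26966 ± 1368 and 11998 ± 1065 CPM. Both genes were picked out after their values were seen, because they led the libraries.

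**Figure D1:**
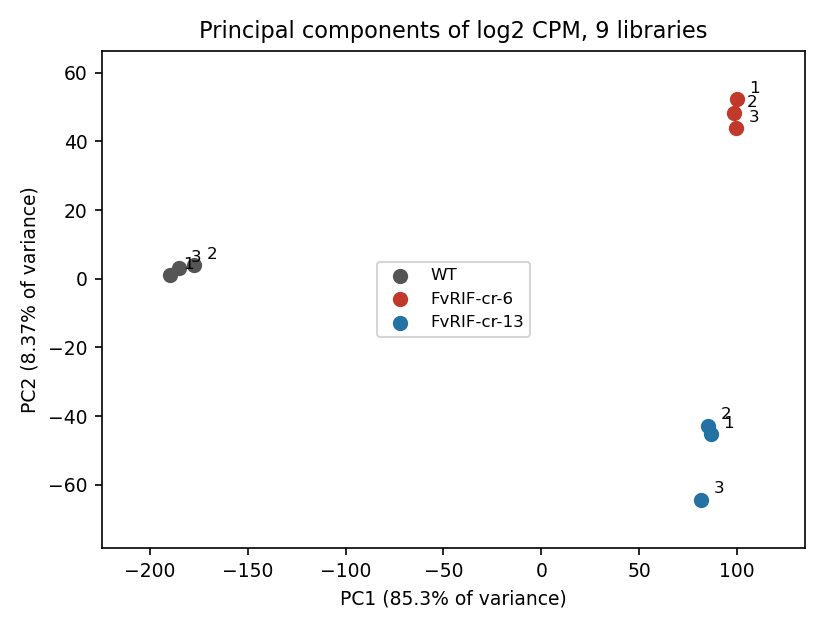
Principal components of log2 CPM for the 9 libraries, with the share of variance of each component on its axis, replicate numbers beside the points and colours for the groups. WT lies between -190 and -177 on the first component and both lines lie at 81.9 or above.

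The mutated gene itself, FvRIF (FvH4_3g20700, chromosome 3, 13762107 to 13763943), was measured at 3011 ± 7.07 CPM in WT, 1869 ± 136 in FvRIF-cr-6 and 1508 ± 91.3 in FvRIF-cr-13. Its log2 fold change was -0.69 (SE 0.06, adjusted p 6.43e-08) in FvRIF-cr-6 and it fell in FvRIF-cr-13 too (adjusted p 7.90e-10), with a log2 difference of -0.31 (SE 0.06) from FvRIF-cr-6. The positions of the mutations are not given in the sources used here, so this RNA level checks neither the mutations nor the protein. FvMYB10 (FvH4_1g22020, chromosome 1, 13950692 to 13952428), a MYB factor that activates anthocyanin genes in strawberry fruit, stood at 14.3 ± 1.27 CPM in WT. It fell to 0.308 ± 0.0283 CPM in FvRIF-cr-6, 45.4-fold lower, and to 0.536 ± 0.245 CPM in FvRIF-cr-13, 26.2-fold lower (adjusted p 4.59e-11 and 1.14e-10).

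The comparison of FvRIF-cr-6 with WT asks which transcripts differ in fruits of that mutant line at 28 days post anthesis. In FvRIF-cr-6, 44 of 46 tested photosynthesis genes rose and 2 fell, with a median log2 fold change of 6.40. The summed level of the list went from 339 ± 16.2 CPM in WT to 5418 ± 62.6 CPM. Its leading members were FvH4_3g02920, an oxygen-evolving enhancer protein of photosystem II, from 0.928 ± 1.18 to 455 ± 14.8 CPM, and FvH4_3g09680, the photosystem I subunit psaK, from 0.0628 ± 0.00240 to 42.7 ± 0.814 CPM. WT had 3 counts of psaK in all, and the ratio of 681 carries a 95% counting interval of 233 to 3302. Of 17 gibberellin genes, 15 rose and 2 fell, among them the gibberellin-inactivating enzyme FvH4_3g38920 (gibberellin 2-beta-dioxygenase 8), which rose 41.8-fold, and FvH4_6g48590, a gibberellin-regulated protein, which rose 35.4-fold. Cell division genes went the other way, with 36 of 59 lower and 13 higher. The kinesin NACK2 (FvH4_1g12070), which acts in cytokinesis, fell 43.4-fold to 2.31 ± 0.472 CPM, and the replication helicase subunit MCM7 (FvH4_5g39230) fell from 33.6 ± 1.97 to 3.06 ± 0.191 CPM.

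These 3 lists stood apart from the other genes by camera with the preset correlation and also with an estimated one. The adjusted p was 5.77e-37 for photosynthesis, 7.87e-07 for gibberellin and 0.000231 for cell division, and 0.0371, 0.0464 and 0.0371 with an estimated correlation. Adjusted over the list alone, 46, 17 and 49 members were called, the same numbers as over all genes. With the 2 photosynthesis members at 0 counts in WT set to their lower bound, the list's median was 6.16.

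Further lists passed with the preset correlation and were lost with an estimated one. Of 73 auxin genes 38 rose and 19 fell (57 adjusted over the list alone; adjusted p = 0.0126, and adjusted p = 0.212 with an estimated correlation). The auxin-response repressors FvH4_6g02870 (IAA4-like) and FvH4_4g02280 (IAA14-like) rose from 0.303 ± 0.423 to 155 ± 12.2 CPM and from 0.281 ± 0.380 to 95.3 ± 1.29 CPM. Of 35 MYB transcription factor genes 27 rose and 5 fell (32 adjusted over the list alone; adjusted p = 0.0126, and adjusted p = 0.229 with an estimated correlation), lost also with Swiss-Prot descriptions (0.0679), among them FvH4_4g35340 (MYB1R1), 20.2-fold higher. Of 40 heat shock protein genes 21 fell and 12 rose (33 adjusted over the list alone; adjusted p = 0.000116, and adjusted p = 0.212 with an estimated correlation). The mitochondrial small heat shock protein FvH4_7g27540 fell from 87.7 ± 7.15 to 1.37 ± 0.337 CPM. Of 154 cytosolic ribosomal protein genes 109 fell and 20 rose (129 adjusted over the list alone; adjusted p = 0.000124, and adjusted p = 0.271 with an estimated correlation). The L24 gene FvH4_6g28810 fell 18.0-fold from 768 ± 12.6 CPM. Of 28 seed storage and late embryogenesis genes, fixed as markers of the achenes on the fruit, 24 rose and 2 fell (26 adjusted over the list alone; adjusted p = 0.0203, and adjusted p = 0.426 with an estimated correlation).

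The seed list did not move evenly through the FvRIF-cr-6 libraries. Of its 28 members, 5 stood at 10 CPM or more in every WT library. Its summed level was 2613 CPM in replicate 1 against 1107 and 1070 CPM in the others, and 2062 to 2185 CPM in WT. The WT sum came mainly from 2 members that fell in both lines, FvH4_5g29270 (a 12S seed storage protein) and FvH4_1g13730 (a vicilin-like gene). Without this pair, a choice made after seeing the values, the sums were 108 to 119 CPM in WT and 2458, 935 and 896 CPM in FvRIF-cr-6. FvH4_4g33760, a peroxygenase, rose from 1.23 ± 0.316 to 58.8 ± 1.91 CPM. With the members at 0 counts in WT at their bound, the list's median log2 fold change was 4.14, against 4.21 as fitted. Read counts of near-identical members of such families, here and among the ribosomal protein genes, are uncertain, since the treatment of reads with several matching positions is not given in the sources used here.

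The remaining lists did not pass in FvRIF-cr-6, with adjusted p from 0.0672 to 0.760. Of 31 anthocyanin pathway genes 17 fell and 10 rose (adjusted p 0.0672). This list passed downward with the 2 groups alone (0.0214), without FvRIF-cr-13 replicate 1 (0.0342) or 3 (0.0172), and without FvRIF-cr-6 replicate 1 and FvRIF-cr-13 replicate 3 (0.0135, chosen after seeing the data). Under the other alternatives its adjusted p went up to 0.0916, and it was 0.271 with an estimated correlation. Their summed level went from 7592 ± 189 to 2113 ± 45.2 CPM. The glucosyltransferase FvH4_7g33840, which adds the sugar that stabilises anthocyanidins, fell 130-fold from 63.0 ± 3.24 CPM, while FvH4_5g00590, annotated as flavonoid 3'-monooxygenase-like, rose 71.2-fold. In Swiss-Prot FvH4_5g00590 is closest to a labd-13Z-ene-9,15,16-triol synthase. Of 10 genes of the proanthocyanidin and flavonol branch 8 rose and 2 fell, and anthocyanidin reductase (FvH4_3g02980), which diverts anthocyanidins to flavan-3-ols, rose 6.11-fold. Pectin-degrading enzymes were split, with 22 of 53 higher and 19 lower, while their summed level went from 21130 ± 167 to 7122 ± 497 CPM. The pectate lyase FvH4_2g19540 and the rhamnogalacturonate lyase FvH4_1g03290, both enzymes that cleave pectin, fell 22.4-fold and 91.0-fold. Of 63 expansins and related wall enzymes 28 rose and 26 fell. Expansin A5 (FvH4_5g14760), a wall-loosening protein, fell 97.5-fold from 672 ± 29.0 CPM, and expansin-like B1 (FvH4_5g20290) rose from 0.128 ± 0.131 to 34.4 ± 8.95 CPM. Volatile formation was split as well, with 31 of 69 higher and 27 lower, and a summed level of 48034 ± 408 CPM in WT and 10244 ± 193 CPM in the line.

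Of the hormone, sugar and pigment lists, 23 of 40 abscisic acid genes rose and 11 fell (adjusted p 0.118, but 0.0410 with Swiss-Prot descriptions and up to 0.302 over the alternatives). The receptor PYL2 (FvH4_2g32040) fell 23.1-fold and an abscisic acid hydroxylase (FvH4_2g34420), which inactivates the hormone, rose 26.7-fold. Of 27 ethylene genes 15 rose and 7 fell, and an oxidase of the last step of ethylene synthesis (FvH4_3g01280) fell 30.1-fold. Of 44 sugar genes 26 rose and 13 fell, led by the transporters FvH4_2g24900 (67.8-fold higher) and FvH4_4g23160 (56.5-fold higher). Of 17 carotenoid genes 10 rose and 3 fell, while the phytoene synthase FvH4_6g38780, the entry enzyme of the pathway, fell from 295 ± 1.78 to 46.9 ± 3.29 CPM. Of 23 ascorbate genes 14 rose and 6 fell, and of 44 lignin genes 20 rose and 11 fell. NAC genes rose in 22 of 42 cases and fell in 16. FvH4_4g31070 was 71.2-fold higher and FvH4_4g23130 10.6-fold lower from 825 ± 16.1 CPM, both annotated as NAC 29 factors in NR. In Swiss-Prot they are closest to NAC domain-containing proteins 1 and 83. Of 28 MADS-box genes 20 rose and 7 fell, and of 81 pathogenesis-related genes 47 rose and 19 fell. The thaumatin-like gene FvH4_6g05880 fell 199-fold and the allergen-like gene FvH4_4g18990 rose 83.9-fold. The 2 inhibitor genes of pectinesterase and polygalacturonase were not called and were too few for a list test; FvH4_6g22790 stood at 7.22 ± 0.870 CPM in WT and 9.20 ± 1.37 in the line (log2 0.35, SE 0.16, adjusted p 0.0618).

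Adjusted over the list alone, the calls were 27 for anthocyanin, 10 for the proanthocyanidin branch, 41 for pectin, 54 for expansins, 58 for volatiles, 35 for abscisic acid, 23 for ethylene, 39 for sugar, 13 for carotenoids, 20 for ascorbate, 31 for lignin, 38 for NAC, 27 for MADS-box, 66 for pathogenesis-related and 0 for the inhibitors. Median and mean were above 0 while the list test pointed down for lignin, pectin, NAC and volatiles. For expansins the median was 0.11, the mean -0.27 and the test direction down.

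Over all 19387 tested genes, 7970 rose and 7207 fell in FvRIF-cr-6, and 5301 and 3589 of them changed at least 2-fold. With total library size in place of TMM factors 66.4% of the calls were higher, against 52.5% here, since the median of all genes moved from 0.07 to 0.41 on the log2 scale. Under that scaling the seed list no longer passed (adjusted p 0.0857), as with Swiss-Prot descriptions (0.0803), and the ribosomal list had 79 lower and 37 higher.

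The comparison of FvRIF-cr-13 with WT asks the same of the second mutant line. Photosynthesis genes again rose in 44 of 46 cases, with a median log2 fold change of 5.98 and a summed level of 4158 ± 178 CPM. FvH4_3g02920 reached 416 ± 15.9 CPM and psaK (FvH4_3g09680) 31.5 ± 1.90 CPM. Gibberellin genes rose in 14 of 17 cases and fell in 1, with FvH4_3g38920 at 27.3-fold and FvH4_6g48590 at 27.8-fold above WT. Cell division genes fell in 36 of 59 cases and rose in 14, NACK2 (FvH4_1g12070) by 22.7-fold and MCM7 (FvH4_5g39230) by 9.73-fold. In this line the anthocyanin list passed the test downward: 19 of 31 genes fell and 6 rose, with FvH4_7g33840 at 0.889 ± 0.680 CPM, 69.8-fold below WT (124-fold without FvRIF-cr-13 replicate 3). The summed anthocyanin level was 2790 ± 154 CPM.

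Photosynthesis and cell division passed with both correlations, at adjusted p 7.23e-36 and 0.000917, and 0.0406 for each with an estimated correlation. Gibberellin passed at 1.08e-06, and its adjusted p = 0.0546 with an estimated correlation. Anthocyanin passed at 0.00684 and was lost at adjusted p = 0.227 with an estimated correlation. Of 10 proanthocyanidin and flavonol genes 7 rose and 1 fell (adjusted p = 0.0375, and adjusted p = 0.227 with an estimated correlation), led by a flavonol synthase 3-like locus on chromosome 5 (12107576 to 12109445) that went from 0.675 ± 0.245 to 55.7 ± 4.46 CPM. This list was lost without FvRIF-cr-13 replicate 3 (adjusted p 0.0581) or that library and FvRIF-cr-6 replicate 1 (0.0566, chosen after seeing the data), without loci whose identifiers are not FvH4 gene numbers (0.222) and with Swiss-Prot descriptions (0.516). The flavonol synthase 3-like locus is closest in Swiss-Prot to 2-oxoglutarate-dependent dioxygenase 19. Of 73 auxin genes 44 rose and 17 fell (adjusted p = 0.00728, and adjusted p = 0.196 with an estimated correlation), with IAA4-like FvH4_6g02870 at 144 ± 12.9 CPM and IAA14-like FvH4_4g02280 at 124 ± 9.63 CPM. Of 35 MYB genes 26 rose and 7 fell (adjusted p = 0.0202, and adjusted p = 0.237 with an estimated correlation). This list was lost also without a low-count filter (0.0643) and with Swiss-Prot descriptions (0.148). Among its members FvH4_4g27090, annotated as MYB24 and closest in Swiss-Prot to MYB62, was 13.7-fold higher. Of 40 heat shock genes 21 fell and 10 rose (adjusted p = 4.97e-05, and adjusted p = 0.225 with an estimated correlation), the class I protein FvH4_7g23650 by 55.9-fold from 212 ± 7.64 CPM. Of 154 cytosolic ribosomal protein genes 98 fell and 24 rose (adjusted p = 0.000403, and adjusted p = 0.390 with an estimated correlation), but 58 fell and 58 rose with total library size in place of TMM factors.

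The other lists did not pass in FvRIF-cr-13, with adjusted p from 0.117 to 0.917. Pectin-degrading enzymes rose in 22 and fell in 20 of 53 cases, and their summed level was 12360 ± 514 CPM. The pectate lyase FvH4_2g19540 fell 8.51-fold and the rhamnogalacturonate lyase FvH4_1g03290 fell 8.23-fold. Expansins and related enzymes rose in 33 and fell in 22 of 63 cases, and expansin A5 (FvH4_5g14760) fell 152-fold. Volatile genes rose in 34 and fell in 28 of 69 cases. The acyltransferase FvH4_2g12510 (benzyl alcohol O-benzoyltransferase) rose 224-fold to 52.8 ± 8.42 CPM (395-fold without WT replicate 3) and the lipoxygenase FvH4_6g34970 rose 33.3-fold, while the summed level of the list fell from 48034 ± 408 to 17593 ± 553 CPM without a test of the sum. Abscisic acid genes rose in 23 and fell in 11 of 40 cases, ethylene genes in 14 and 7 of 27, sugar genes in 26 and 14 of 44, and carotenoid genes in 9 and 4 of 17. FvH4_5g38040, annotated as a homolog of 1-aminocyclopropane-1-carboxylate oxidase, rose 11.6-fold, and a carotenoid cleavage dioxygenase (FvH4_2g35670) rose 79.7-fold (137-fold without WT replicate 2). The Swiss-Prot match of FvH4_5g38040 is 2-oxoglutarate-dependent dioxygenase 19. Ascorbate genes rose in 14 and fell in 7 of 23 cases, with an ascorbate oxidase (FvH4_5g29070) 8.70-fold and an ascorbate peroxidase (FvH4_1g11490) 3.74-fold higher. Lignin genes rose in 22 and fell in 15 of 44 cases. A hydroxycinnamoyltransferase (FvH4_3g06690) rose 73.6-fold and FvH4_7g01570, annotated as cinnamoyl-CoA reductase 1-like and closest in Swiss-Prot to a phenylacetaldehyde reductase, fell 39.2-fold from 366 ± 26.9 CPM.

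NAC genes rose in 22 and fell in 14 of 42 cases, MADS-box genes in 17 and 8 of 28, and pathogenesis-related genes in 49 and 17 of 81. The MADS-box genes FvH4_5g05030 and FvH4_5g08530 rose 67.6-fold and 124-fold (the latter 209-fold without WT replicate 2). The inhibitor FvH4_6g22790 rose 1.81-fold and the other tested inhibitor was not called. Seed storage and late embryogenesis genes rose in 8 and fell in 4 of 28 cases (12 adjusted over the list alone; adjusted p 0.715). Their summed level was 624 to 688 CPM per library against 2062 to 2185 CPM in WT, and their median log2 fold change was 1.05 as fitted and 0.43 with members at 0 counts at their bound. Without FvH4_5g29270 and FvH4_1g13730, a choice made after seeing the values, the sums were 313 to 349 CPM against 108 to 119 CPM in WT. Adjusted over the list alone, the calls were 46 for photosynthesis, 15 for gibberellin, 50 for cell division, 25 for anthocyanin, 8 for the proanthocyanidin branch, 61 for auxin, 33 for MYB, 31 for heat shock and 122 for ribosomal proteins. They were 42 for pectin, 55 for expansins, 62 for volatiles, 35 for abscisic acid, 21 for ethylene, 40 for sugar, 13 for carotenoids, 21 for ascorbate, 37 for lignin, 36 for NAC, 25 for MADS-box, 68 for pathogenesis-related and 1 for the inhibitors. Median and mean were above 0 while the list test pointed down for lignin, pectin and NAC.

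Over all 19387 tested genes, 7946 rose and 7042 fell in FvRIF-cr-13, with 5245 and 3444 changed at least 2-fold. With total library size 70.1% of the calls were higher, against 7946 of 14988 here, and the median of all genes moved from 0.09 to 0.51 on the log2 scale.

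**Figure D2:**
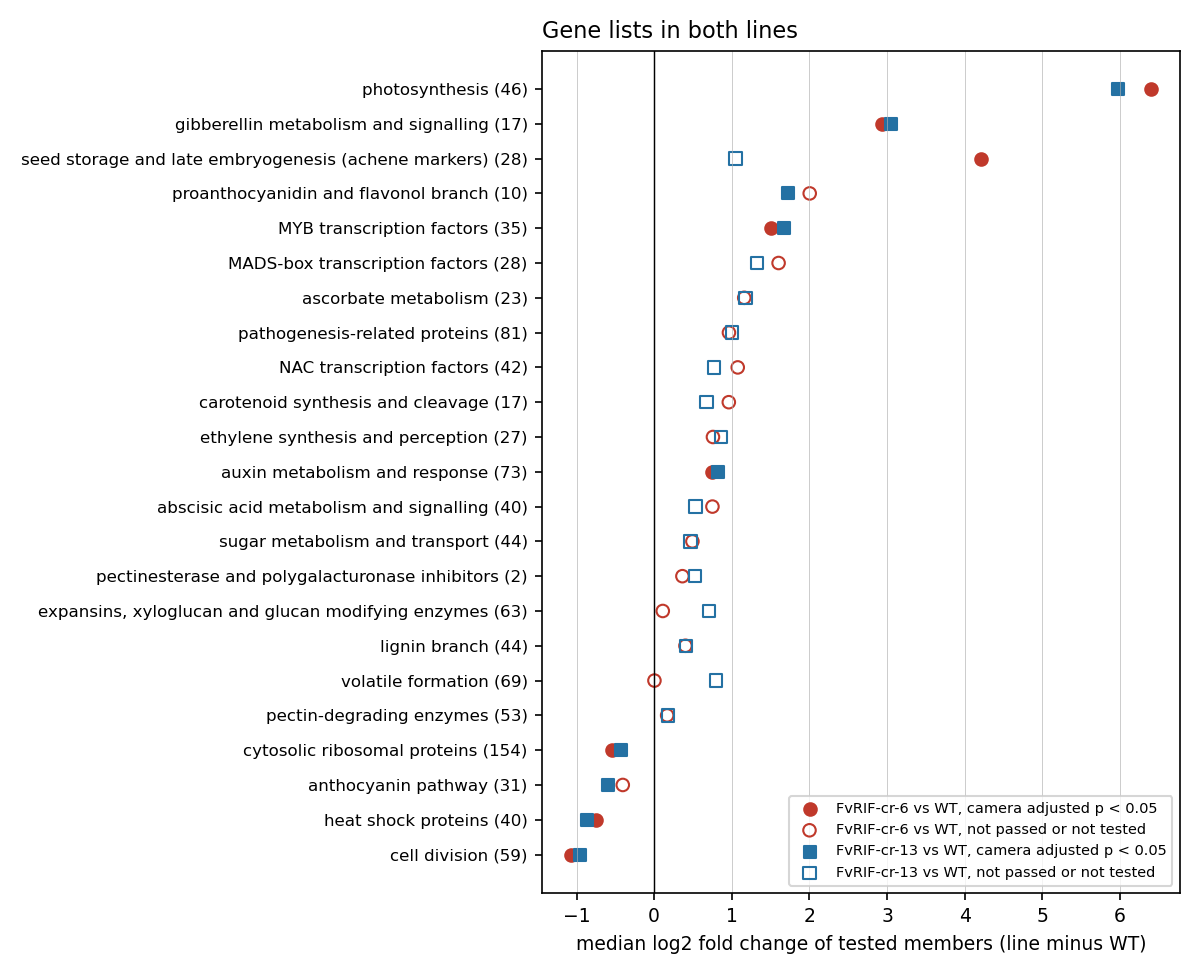
Median log2 fold change against WT of the tested members of each gene list (number of members in brackets) in FvRIF-cr-6 (circles) and FvRIF-cr-13 (squares), filled where the camera adjusted p was below 0.05 with the preset correlation. Photosynthesis lies at 6.40 and 5.98 and cell division at -1.07 and -0.95; with total library size the ribosomal list was even in FvRIF-cr-13, with 58 higher and 58 lower.

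Both mutant lines were then compared for the genes they shared. The genes that rose most in both lines included FvH4_7g17800 (CURVATURE THYLAKOID 1B, a protein that shapes thylakoid membranes) and FvH4_4g07760 (uncharacterized), each with 0 counts in WT. Against a floor of 3 counts over the group, which is 0.0627 CPM in WT, they were at least 621-fold and 287-fold higher in FvRIF-cr-6 and at least 298-fold and 324-fold higher in FvRIF-cr-13. FvH4_6g11940, an acyltransferase annotated as DCR, had 1 count in WT, 37.8 ± 0.801 CPM in FvRIF-cr-6 and 120 ± 27.0 CPM in FvRIF-cr-13. Its ratio to WT was 1809 (95% counting interval 324 to 71473) and 5711 (1025 to 225615). The cytochrome P450 gene FvH4_6g53330 also had 1 count in WT, and its ratios were 1022 (183 to 40398) and 937 (168 to 37033). FvH4_6g30880, a ring-cleavage dioxygenase, rose from 0.0861 ± 0.1005 CPM in WT to 56.7 ± 1.41 and 55.0 ± 1.99 CPM. Its fitted folds, 631 and 611, rest on few WT counts and became 1540 and 1493 without WT replicate 2.

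The deepest falls shared by both lines were taken among annotated genes with a mean of at least 10 CPM over all 9 libraries. A gene near 0 in both lines can meet this limit only if it is well expressed in WT. The ammonium transporter FvH4_2g20250 went from 30.4 ± 1.52 CPM to 0 counts in both lines, at least 657-fold lower in FvRIF-cr-6 and at least 676-fold lower in FvRIF-cr-13. FvH4_1g19240, a probable mannitol dehydrogenase, went from 328 ± 6.03 to 0.154 ± 0.0243 and 0.107 ± 0.186 CPM. FvH4_7g04660 (uncharacterized, chromosome 7, 5155734 to 5156643) and its neighbour FvH4_7g04670 (a 60S ribosomal protein L27-like gene, 5156876 to 5159545) fell together. The former went from 405 ± 27.3 to 1.18 ± 0.113 and 0.0146 ± 0.0253 CPM, the latter from 261 ± 20.7 to 0.553 ± 0.158 and 0.178 ± 0.272 CPM. With 1 count in FvRIF-cr-13, the former's ratio there was 27134, with a 95% counting interval of 4869 to 1071790. FvH4_4g26740 (uncharacterized in NR, closest in Swiss-Prot to transcription factor bHLH23) was at least 2285-fold lower in FvRIF-cr-13, where it had 0 counts. In FvRIF-cr-6 it stood at 0.108 ± 0.0972 CPM (fitted 900-fold lower, 1368-fold without FvRIF-cr-6 replicate 2). An uncharacterized locus on chromosome 6 (17230202 to 17234435) was at least 1278-fold lower in FvRIF-cr-6, with 0 counts, and stood at 0.0736 ± 0.0671 CPM in FvRIF-cr-13 (fitted 728-fold lower, 1138-fold without FvRIF-cr-13 replicate 3). These intervals and floors cover counting error only.

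In all, 13266 genes changed in both lines in the same direction, 6997 upward and 6269 downward, and 179 changed in opposite directions. Of them 4606 rose and 2866 fell at least 2-fold in both. Independent lists of the same lengths would share 3266.6 upward and 2617.82 downward. Fold changes of the lines correlated across genes at r = 0.934, where genes are not independent replicates, and 90.2% had the same sign. Simulated unchanged groups against the same WT libraries gave r = 0.534 and 67.5% on average over 20 runs. Those runs had 0 genes called in both by edgeR, and 185 on average at an unadjusted p below 0.05. The covariance was 5.46 against 0.0271 simulated, a difference of 5.43. In the simulated runs the spread between the WT libraries gave little covariance, which argues against that spread as the main source of the observed value. A difference common to all WT libraries would enter both comparisons and was not simulated, so it may still add to the excess. The WT libraries are too few to be split into sets of at least 2.

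The comparison of the lines with each other asks where FvRIF-cr-13 and FvRIF-cr-6 differ. Several genes were near silence in FvRIF-cr-6 and expressed in both other groups. The fatty acid desaturase FvH4_3g44270, an enzyme that makes linoleic acid, stood at 0.463 ± 0.248 CPM in FvRIF-cr-6 against 962 ± 15.1 in WT and 213 ± 16.9 in FvRIF-cr-13. The homeobox gene FvH4_1g20230 (ATHB-6-like, chromosome 1, 12443386 to 12446125) stood at 1.38 ± 0.0619 CPM against 194 ± 0.900 and 333 ± 20.5. The uncharacterized locus beside it (12431523 to 12438157) had 0 counts in FvRIF-cr-6 and 23.7 ± 5.14 CPM in FvRIF-cr-13, at least 516-fold more. The beta-galactosidase gene FvH4_1g09190 stood at 0.386 ± 0.188 CPM in FvRIF-cr-6 against 117 CPM in WT (113 to 121 per library) and 85.8 ± 3.31 in FvRIF-cr-13, and the receptor-like gene FvH4_3g45620 at 0.306 ± 0.128 CPM against 33.1 ± 2.20 and 16.3 ± 2.44.

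The genes that were lowest in FvRIF-cr-13 relative to FvRIF-cr-6 included 3 seed storage globulins. FvH4_2g21400 (12S globulin), FvH4_2g21390 (cruciferin-like) and FvH4_3g19080 (legumin B-like) stood at 290 ± 395, 245 ± 272 and 68.1 ± 86.6 CPM in FvRIF-cr-6 and at 0.583 ± 1.01, 2.21 ± 3.55 and 0.153 ± 0.266 CPM in FvRIF-cr-13. FvRIF-cr-6 replicate 1 carried most of these levels, with 745, 559 and 168 CPM against 59.5 to 64.1, 83.3 to 92.9 and 16.6 to 19.6 CPM in the other replicates. FvH4_7g04660 and FvH4_4g33950 (annotated as a 21 kDa protein) had 1 and 0 counts in FvRIF-cr-13 and 77 and 15 counts in FvRIF-cr-6. Of the whole seed list, 23 of 28 genes were lower in FvRIF-cr-13 and 1 higher (25 adjusted over the list alone; median -3.02; adjusted p = 1.78e-11, and adjusted p = 0.209 with an estimated correlation).

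The median was above 0 and the mean below it, or the test pointed the other way, for the ethylene, NAC, MYB and heat shock lists, none of which passed. The list test was added to this comparison after the data had been seen. Volatile genes were higher in FvRIF-cr-13 in 30 of 69 cases and lower in 6 (37 adjusted over the list alone; median 0.28; adjusted p = 4.60e-05, and 0.0425 with an estimated correlation), and the acyltransferase FvH4_2g12510 was 2.61-fold higher. The expansin list passed upward (17 higher, 15 lower of 63; 34 adjusted over the list alone; median 0.02; adjusted p = 0.00181, and 0.0425 with an estimated correlation). Photosynthesis genes were lower in 24 of 46 cases and higher in 1 (28 adjusted over the list alone; adjusted p = 0.000102, and adjusted p = 0.287 with an estimated correlation). Abscisic acid genes were lower in 15 of 40 cases and higher in 4 (20 adjusted over the list alone; adjusted p = 0.00373, and adjusted p = 0.209 with an estimated correlation). Anthocyanin genes were lower in 14 of 31 cases and higher in 6 (20 adjusted over the list alone). Camera gave adjusted p = 0.0406, and adjusted p = 0.209 with an estimated correlation. The summed level of this list went the other way, without a test of the sum. It was 2790 ± 154 CPM in FvRIF-cr-13 and 2113 ± 45.2 CPM in FvRIF-cr-6. Pectin genes were higher in 18 of 53 cases and lower in 13 (33 adjusted over the list alone; adjusted p = 0.0449, and adjusted p = 0.220 with an estimated correlation), and the rhamnogalacturonate lyase FvH4_1g03290 was 11.1-fold higher.

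Over all genes, 3361 were higher and 3415 lower in FvRIF-cr-13 than in FvRIF-cr-6, with 904 and 801 at least 2-fold apart. Among genes called, FvRIF-cr-13 vs FvRIF-cr-6 gave 4526 higher and 2715 lower with total library size alone. Of the 13266 genes changed alike in both lines 4610 also differed between them, 2740 of them farther from WT in FvRIF-cr-6 and 1870 farther in FvRIF-cr-13.

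**Figure D3:**
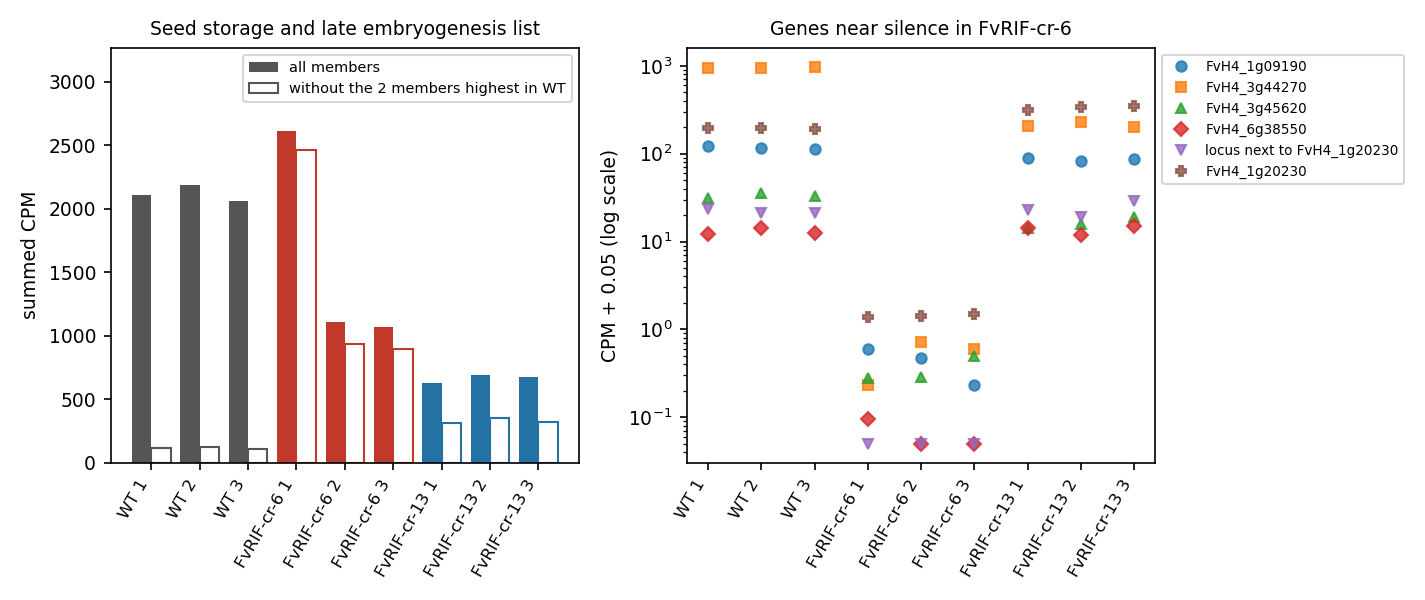
Left, summed CPM of the seed storage and late embryogenesis list in each of the 9 libraries, with all members (filled bars) and without the 2 members highest in WT (open bars). Right, CPM + 0.05 on a log scale of 6 genes near silence in FvRIF-cr-6; FvRIF-cr-6 replicate 1 reaches 2613 CPM on the left, and FvH4_3g44270 stands at 0.463 ± 0.248 CPM in FvRIF-cr-6 on the right.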

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

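The values in this part set the effects of both lines against the same WT apart by a test of the difference itself, FvRIF-cr-13 minus FvRIF-cr-6; the list tests between the lines, the splits of the libraries and the tests on seed transcripts and on genes near silence were chosen only after the results were seen. In all, 6776 genes differed. Of the 10 splits of the 6 mutant libraries, 1 (the real one) gave as many genes as the 6105 that a fit on these groups alone calls; the highest other split gave 0 by edgeR (316 at an unadjusted p below 0.05), and 10 splits are too few for a share under 0.05.

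The following groups of genes differed between the lines by camera with the preset correlation, by their median log2 difference: seed storage and late embryogenesis (-3.02), photosynthesis (-0.35), anthocyanin (-0.26), abscisic acid (-0.24), volatile formation (0.28), pectin degradation (0.0285) and expansins with related wall enzymes (0.0164). With an estimated correlation only the volatile and expansin lists passed (adjusted p 0.0425 each). The other 5 were lost (0.209 for seed storage, anthocyanin and abscisic acid, 0.220 for pectin and 0.287 for photosynthesis). Opposite to its median, the summed anthocyanin level was higher in FvRIF-cr-13, at 2790 ± 154 CPM against 2113 ± 45.2 CPM in FvRIF-cr-6.

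Among genes listed by pigment and phenylpropanoid descriptions the log2 difference was -0.60 for the flavonoid 3'-monooxygenase-like gene FvH4_5g00590 and -0.66 for anthocyanidin reductase FvH4_3g02980. It was 1.79 for the flavonol synthase 3-like locus on chromosome 5 (12107576 to 12109445) and 1.27 for the cinnamoyl-CoA reductase 1-like gene FvH4_7g01570. Of these, only anthocyanidin reductase has a Swiss-Prot match to the same enzyme. FvRIF itself (FvH4_3g20700) differed by -0.31. Of the wall genes, the rhamnogalacturonate lyase FvH4_1g03290 differed by 3.47, the pectate lyase FvH4_2g19540 by 1.40, the polygalacturonase inhibitor FvH4_6g22790 by 0.51, expansin A5 FvH4_5g14760 by -0.64 and expansin-like B1 FvH4_5g20290 by -2.71. Of the hormone genes, the abscisic acid hydroxylase FvH4_2g34420 differed by -0.99, the receptor FvH4_2g32040 by 0.73, IAA14-like FvH4_4g02280 by 0.38, the gibberellin genes FvH4_3g38920 and FvH4_6g48590 by -0.62 and -0.35, and the oxidase homolog FvH4_5g38040 by 0.78. The sugar transporter FvH4_4g23160 differed by -1.05, the acyltransferase FvH4_2g12510 by 1.39, psaK FvH4_3g09680 by -0.44 and the ascorbate peroxidase FvH4_1g11490 by -0.49.

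Of the transcription factors, NAC 29-like FvH4_4g31070 and NAC 29 FvH4_4g23130 differed by -1.37 and -1.16, and the MADS-box genes FvH4_5g05030 and FvH4_5g08530 by -2.22 and 1.02. The heat shock gene FvH4_7g23650 differed by -0.38, the thaumatin-like gene FvH4_6g05880 by 2.46, the allergen-like gene FvH4_4g18990 by -1.36 and the kinesin NACK2 FvH4_1g12070 by 0.94. CURVATURE THYLAKOID 1B FvH4_7g17800 differed by -1.06 and the acyltransferase FvH4_6g11940 by 1.66. For genes with 0 or 1 counts in a line the fitted value depends on the prior count. FvH4_4g26740 (fitted -4.19, and -3.57 without FvRIF-cr-6 replicate 2) and FvH4_4g33950 (fitted -5.24) were at least 2.40-fold and 5.14-fold lower in FvRIF-cr-13, and FvH4_7g04660 (fitted -5.81, and -7.55 without FvRIF-cr-13 replicate 3) was lower by a ratio of 79.2 (95% counting interval 13.8 to 3169).

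Seed storage genes formed the first pattern: FvH4_2g21400 differed by -8.98, FvH4_3g19080 by -8.77 and FvH4_2g21390 by -6.82 (-6.75, -6.86 and -5.34 without FvRIF-cr-6 replicate 1; fitted -15.48, -13.39 and -10.57 without FvRIF-cr-13 replicate 2; -8.38 for the first without FvRIF-cr-13 replicate 3). Against the idea that FvRIF-cr-6 replicate 1 alone carries the difference, 23 members of the list were still called lower in FvRIF-cr-13 without it. Over the 16 members above 10 CPM the ratio of replicate 1 to the other replicates had a median of 1.46, from 0.869 to 11.97. Several of these are expressed in the other groups too and FvH4_5g29270 and FvH4_1g13730 are highest in WT, so the ratios do not show what share seed tissue had. Different amounts of achene tissue, or achenes at different stages of seed filling, may underlie the pattern and stay open.

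Genes near silence in FvRIF-cr-6 formed the second pattern: the uncharacterized locus on chromosome 1 (12431523 to 12438157; fitted 11.89, at least 516-fold), the desaturase FvH4_3g44270 (8.83), the homeobox gene FvH4_1g20230 (7.90), the beta-galactosidase gene FvH4_1g09190 (7.78) and FvH4_3g45620 (5.70). FvH4_6g38550, an ER membrane complex subunit gene singled out after its values were seen, went from 12.9 ± 1.06 CPM in WT to 0.0153 CPM in FvRIF-cr-6 and 13.7 ± 1.78 in FvRIF-cr-13. Away from the chromosome 1 pair, the 40 tested genes flanking 4 such loci had a median difference of 0.0640 (quartiles -0.23 and 0.49). This argues against the view that all 4 loci lie in lost blocks over most of the 5 tested genes on each side. The flanking genes were pooled, so the median cannot exclude such a block at a single locus. A loss of 1 or 2 genes stays open too, since the locus beside FvH4_3g44270 differed by 4.64. For the pair, FvH4_1g20230 kept 0.713% of its WT level in FvRIF-cr-6 (90 counts), and whether a block with both genes was lost cannot be told apart from lower expression. The genes on either side differed by 0.42 and -0.00950 between the lines. Differences in genetic makeup of the line outside FvRIF were not tested, as no sequence was used here.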

How the results depend on the processing

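Leaving out loci without FvH4 gene numbers, and leaving out FvRIF-cr-6 replicate 1 with FvRIF-cr-13 replicate 3, were alternatives chosen after the data were seen. Of genes called, FvRIF-cr-6 vs WT had 14687 to 15834 with each library left out in turn; of genes called, FvRIF-cr-13 vs WT had 14456 to 15226, and of genes called, FvRIF-cr-13 vs FvRIF-cr-6 had 5368 (without FvRIF-cr-6 replicate 1) to 6592. The genes called in both lines, same direction, numbered 12749 to 13743, and the lists 8 to 9 in each line. DESeq2, other factors, other filters, the 2 groups alone and the later alternatives stayed within 1.5 times of each count, such as 14978, 14830, 6575 and 13135 with DESeq2 in the order above. Against a fold of 1.5 (glmTreat) the counts were 9991 in FvRIF-cr-13, 1418 between the lines and 8584 in both, by construction a stricter question. With an estimated correlation 3 lists passed in FvRIF-cr-6 and 2 in FvRIF-cr-13. Of the values of the named genes under alternatives 3085 kept direction and side of the threshold, 33 lost the call, 9 gained it and 5 changed sign; of those of the 17 list results that passed 285 kept both and 21 lost the call. Of lists that had not passed, anthocyanin gained it in 4 alternatives (adjusted p 0.0135 to 0.0342) and abscisic acid in 1 (0.0410), all in FvRIF-cr-6 vs WT. The sign changes are all in FvRIF-cr-13 vs WT, for genes not called there. Without FvRIF-cr-13 replicate 2, which held most of their few counts, the globulins went to -4.38 (FvH4_2g21400), -3.45 (FvH4_3g19080) and -2.65 (FvH4_2g21390), and their highest values, without WT replicate 2, were 6.56, 4.68 and 1.80. The locus beside FvH4_1g20230 went to -0.0458 without FvRIF-cr-13 replicate 3 and -0.0432 without both libraries, and to 0.266 without FvRIF-cr-13 replicate 2; the cause was not tested. With a replicate block 6518 genes differed between the lines. Departures from the group means correlated at 0.0537, -0.00100 and 0.0997 for libraries with the same number. For libraries with different numbers the correlations ran from -0.0848 to 0.0498. So few values do not settle whether the numbers pair the libraries. No paired analysis was made for the comparisons with WT, because the numbers in the WT column headings are not tied to WT samples by the labels. Of the 10 splits of the libraries of each line with WT, 1 (the real one) gave as many genes (15255 and 14543 on these groups alone; highest other 0 by edgeR, with 17 and 63 at an unadjusted p below 0.05), and 10 splits are too few for a share under 0.05. For both lines, 1 of 100 splits of the 9 libraries into 3 groups, the real one, gave as many (13266, highest other 12577). That is the smallest share 100 splits can give, since the real split was among them. Splits that mix WT with mutant libraries widen the spread within groups, so the share does not exclude chance. The splits that kept WT whole and mixed the mutant libraries gave 12567 to 12577. Most of the number thus does not depend on which mutant library belongs to which line. The next highest, 2894, kept all groups whole with FvRIF-cr-13 in the place of WT.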

Other observations

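The protein families, the sets of loci on in one group and silent in another, the retroelement loci and the test on neighbouring loci were chosen only after the results were seen. Single protein families are given here by the calls of their members. Of 98 genes with a TIR domain 76 rose in FvRIF-cr-6 and 79 in FvRIF-cr-13 (medians 1.71 and 1.71), and of 141 with an NB-ARC domain 96 and 103 rose. Lipoxygenases rose in 10 of 12 cases in each line (medians 3.48 and 3.43), and tify-domain genes in 8 of 10. Of the families lower in both lines, 16 of 18 proteasome subunit genes fell in each line (medians -1.52 and -1.29), as did 15 of 17 core histone genes (-1.41 and -1.24) and 15 and 14 of 16 TCP-1 chaperonin genes. In all, 28 of 293 families with at least 10 members passed in both lines with the preset correlation, 15 upward and 13 downward. With an estimated correlation camera called 0 in both lines, with 16 at an unadjusted p below 0.05 and adjusted p for the 28 from 0.227 to 0.725.

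Loci of retroelement type did not all move one way. Of 33 loci with a transposon description 15 were higher and 9 lower in FvRIF-cr-6, and 16 and 9 in FvRIF-cr-13. Of 27 loci with a retrotransposon gag or reverse transcriptase RNase H domain 20 fell and 3 rose in both lines, and 8 had 0 counts in both lines. The 21 loci that share the description LOC101312974, on all 7 chromosomes, fell in both lines, from 0.732 to 42.0 CPM in WT, and 15 of them had 0 counts in both lines. Of these 21, 9 are also among the 27, and all 9 fell in both lines, 8 of them to 0 counts in both. None of the 27 and none of the 21 carries an FvH4 gene number. Reads shared between such copies are not resolved by these counts.

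The third pattern is a set of 90 loci at 10 CPM or more in every WT library and under 1 CPM throughout both lines. Of these, 42 (46.7%) carry identifiers other than FvH4 gene numbers. That share was 5.38% among the 12857 loci at 10 CPM or more in any library, which is a wider criterion. At a limit of 0.3 CPM the set had 44 loci, 26 of them of that kind. Of the loci on in both lines and under 1 CPM in WT, 8 of 175 were of that kind, a share that differs from 42 of 90 (Fisher p 4.88e-16). Of 1565 tested loci of that kind 37.8% fell in both lines and 30.8% rose, and of loci with FvH4 gene numbers 31.9% fell in both. The 37.8% stays below the bound set beforehand for an assembly of the class mainly from WT reads. It cannot tell whether the 42 loci themselves were assembled that way, so this explanation stays open for them. A difference in genetic background between WT and the lines may play a part and stays open: the set held 2 adjacent pairs, where random draws gave 0.501 on average and 882 of 10000 draws gave as many, and 0 pairs among its 48 loci with FvH4 gene numbers. The 175 loci silent in WT held 5 pairs against 1.64 on average (242 of 10000 draws as many; 148 for the 167 with FvH4 gene numbers, also 5 pairs). Higher activity of transposon loci in WT stays open too. The loci with a transposon description did not move as a set (larger camera p 0.736), a bound set before that result was seen. The 22 DNA methylation genes did not either, with 8 higher and 8 lower in FvRIF-cr-6 (camera p 0.571) and 8 higher and 5 lower in FvRIF-cr-13 (0.801), so that part of the explanation was not seen. The bound on the loci may miss such elements, because the description list holds only 3 of the 27 loci with the domains above. Of those 27, 20 fell in both lines. Both domains were taken up after the results were seen, and their families passed downward in both lines with the preset correlation. Their fall is therefore no independent test of the bound. Only 4 of the 27, and 3 of the 21 LOC101312974 loci, belong to the set of 90. Of the 20 that fell, 16 lie outside this set, so they do not bear on it directly.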
